A study of Mus musculus with 88 samples.

How the data were processed

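The series holds 88 Affymetrix expression arrays of Pink1 knockout (KO) and wild-type (WT) mice. Tissues were striatum, midbrain and cerebellum at 6 weeks, 12 weeks, 24 weeks and 18 months, and liver at 6, 12 and 24 weeks. Each of the 30 groups of tissue, age and genotype held 3 arrays, apart from the 12-week wild types of midbrain and of liver, which held 2. The text that accompanies the series calls the wild types littermates, which the sample labels do not state. It gives the third age as 14 weeks and leaves liver out, while the labels give 24 weeks and include liver. The labels were followed. They do not state whether each array is a separate animal, nor whether tissues of the same number come from the same animal, so every p below measures only the spread between arrays.

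Per the labels' protocols, RNA was extracted with the RNeasy Midi kit and biotinylated cRNA was prepared from 1 ug of total RNA by the Affymetrix protocol. Per the submitters' processing notes, RMA, limma and R 2.7.0 were used. Their roles, the versions of RMA and limma, and which arrays were normalized together are not given in the sources used here. The deposited values are log2 probe set signals, between 2.14 and 15.39, and were used as deposited. Liver arrays had another distribution (array means 5.45 to 5.53) than brain arrays of 6 to 24 weeks (6.46 to 6.50), so no liver value was compared with a brain value. The file held 45101 probe sets, of which 64 control probe sets were left out and 45037 were tested without a filter on signal. Of these, 34945 carried exactly 1 gene symbol (18194 genes), 932 carried several and 9160 carried none. Symbols came from the platform annotation supplied for the array. Probe sets with several symbols or none were counted and not named. Where a gene had several probe sets, each was tested by itself. The text says for some genes how many passed, and a difference named for the others may sit on 1 probe set.

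Differences were tested in R 4.3.3 with limma 3.58.1 (linear model, moderated statistic, Benjamini-Hochberg adjustment over all probe sets, threshold 0.05, both directions). All arrays of a tissue were fitted together with 1 mean per age and genotype and no block, which left 16 residual degrees of freedom in striatum and cerebellum, 15 in midbrain and 11 in liver. Contrasts were KO minus WT at each age (15 combinations), KO minus WT averaged over ages, an F test of whether the KO minus WT difference varied with age, the difference between its 18-month and 6-week values in brain, and age against 6 weeks averaged over genotypes. A fit over the 71 brain arrays tested by F whether the averaged difference varied between regions. Fold changes are log2 with the standard error (SE) of the fit, and group levels are log2 mean ± SD with n = 3 unless another n is given.

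Gene lists were fixed before the data were examined, as were the tests and the rule for named genes. There were 40 lists with 789 genes, 704 of them on the array, covering mitochondria, Parkinson disease, neuron and glia types, neighbouring tissues, stress, metabolism and liver functions. Of these 35 were tested in each brain region and 28 in liver, each on the probe set of highest mean per gene, with limma's camera test (preset correlation 0.01, at least 5 measured genes, adjusted over the lists of a tissue). Camera with an estimated correlation and the fry test were alternatives. In the text a list "shifted" where camera passed, while single genes rose or fell only where their own test passed. A count "adjusted over the list alone" adjusts over that list's genes.

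The named genes followed a fixed rule with 7 parts. They were Pink1, the 8 genes that rose most and the 8 that fell most on average over ages with the same sign at every age (in liver, where fewer than 5 passed, the 5 with the smallest p), up to 20 genes that passed in at least 2 tissues, the 3 that rose and the 3 that fell most at each age, the 5 with the smallest p in each F test, the 5 that rose and the 5 that fell most in each age effect, and up to 4 members of a list with the smallest p. A gene outside this rule is said to be chosen after its values were seen.

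The procedure was tested on simulated data with the design of striatum and liver, with 200 of 45037 probe sets changed. It found 91% of changes of 0.5 log2 and 99% of changes of 1 log2 in the striatum average, 45% and 90% at a single age in striatum, and 41% and 74% in the liver average. In the F test over ages these shares were 9% and 70% in striatum and 0% and 13% in liver. With no change it called 0 probe sets in either tissue. The shifted list was found in both, and 0 other lists were called. False calls were 14 of 204 in the striatum average, 20 of 196 in its 24-week age effect and 5 of 120 in the liver average. Noise was drawn independently for each probe set, without correlation between genes or differences between whole arrays. The simulation therefore does not measure error on the real arrays. There, splits other than the real one reached 6079 probe sets in cerebellum at 24 weeks and 18 lists in its genotype average.

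The 75 alternatives chosen before the data were seen covered quantile normalization between arrays, a filter on low signal, 1 probe set per gene, a trended and robust prior, array weights, covariates for the Gapdh 3' minus 5' control difference and for Xist, fits of single ages, 1 genotype only for age, other list tests, a replicate block, and leaving out each array. Counts were also made for other splits of the samples (all 10 splits for 3 against 3 arrays, otherwise 100 drawn with seed 1). Chromosome order from the GRCm38.p6 annotation served only to ask which genes neighbour each other. No sample was left out of the reported fits.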

Results

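Pink1, the mitochondrial protein kinase whose loss causes an inherited form of Parkinson disease, fell in the knockout in every tissue and at every age. In striatum the first of 2 probe sets fell by 4.43 log2 on average over ages (SE 0.05, adjusted p = 2.07e-24), in midbrain by 4.05 (SE 0.06, adjusted p = 4.9e-21), in cerebellum by 4.26 (SE 0.11, adjusted p = 1e-16) and in liver by 4.97 (SE 0.10, adjusted p = 2.86e-12). Its signal lay between 6.31 and 6.75 on the KO arrays of striatum and between 10.78 and 11.44 on the WT arrays. The ranges of the 2 genotypes did not overlap in midbrain (6.78 to 7.28 and 10.75 to 11.28), cerebellum (5.61 to 7.02 and 10.68 to 11.21) or liver (4.18 to 5.26 and 9.42 to 9.79). The fall at single ages ran from -4.08 at 6 weeks to -4.72 at 18 months in striatum, -3.97 to -4.09 in midbrain, -4.08 to -4.58 in cerebellum and, up to 24 weeks, -5.31 to -4.52 in liver. The second Pink1 probe set fell by 4.02, 3.83, 3.91 and 4.59 on average in striatum, midbrain, cerebellum and liver. The measured Pink1 signal thus placed all 88 arrays on the side of their genotype label.

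**Figure D1:**
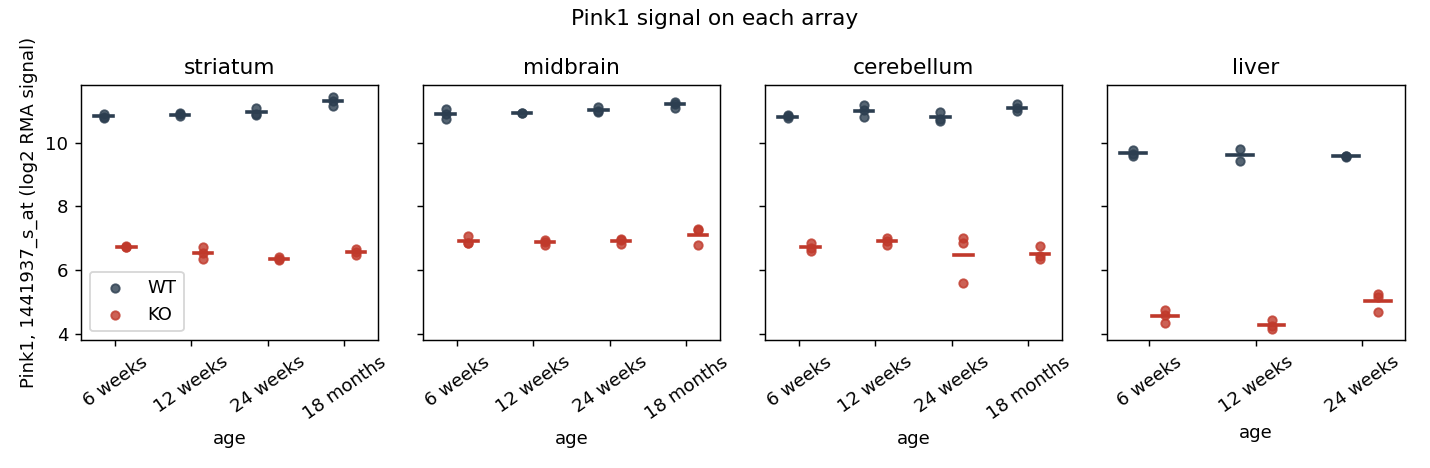
Pink1 signal (first probe set, log2) on each of the 88 arrays by age in 4 tissues, with WT and KO arrays as points and group means as bars. KO arrays of striatum lie between 6.31 and 6.75 and WT arrays between 10.78 and 11.44, and the genotypes do not overlap in any tissue.

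Besides Pink1, the largest averaged differences shared by the brain regions were a fall of Phgdh, the first enzyme of serine synthesis from glycolysis, and a rise of Tia1, an RNA-binding protein of stress granules. Phgdh fell by 3.31 log2 in striatum (SE 0.14, adjusted p = 3.7e-12), by 3.28 in midbrain (SE 0.12, adjusted p = 3.13e-13) and by 2.73 in cerebellum (SE 0.13, adjusted p = 7.87e-12). Tia1 rose by 3.51 (SE 0.30, adjusted p = 5.2e-07), 3.61 (SE 0.33, adjusted p = 2.16e-06) and 3.50 (SE 0.31, adjusted p = 1.18e-06). Clta, the clathrin light chain of vesicle coats, fell by 1.63, 1.64 and 1.63, and Erc1, a scaffold protein of the presynaptic active zone, fell by 0.90, 1.15 and 2.46. Srrm1, of messenger RNA splicing, rose by 0.95, 0.84 and 1.24, and 1 probe set of Hnrnpr, which binds RNA, rose by 0.77, 0.87 and 0.72. The splicing factor Isy1 rose by 0.34, 0.38 and 0.43, while the splicing factor Srsf10 fell by 0.76, 0.50 and 0.73. Pnrc2, a coactivator in messenger RNA decay, rose by 0.66, 0.64 and 0.42, and Glo1, which detoxifies methylglyoxal, by 0.28, 0.34 and 0.35. Mid1, an X-linked ubiquitin ligase, fell by 0.83, 1.01 and 0.79. Falls were also seen for the chemokine gene Ccl27a (by 0.73, 0.64 and 0.82), the non-coding Cep83os (by 0.82, 0.40 and 1.13), Sbsn (by 0.55, 0.46 and 0.41) and the progestin receptor gene Paqr7 (by 0.23, 0.29 and 0.43). Passing in 2 regions, with no test against the third given here, Pithd1 rose in midbrain (0.27) and cerebellum (0.28) and Zfp9 fell in striatum (-0.32) and midbrain (-0.31). Likewise Sike1 (-0.32 and -0.40) and the iron-sulfur cluster gene Nfu1 (-0.33 and -0.41) fell in striatum and cerebellum, while Sike1 lay at 0.05 in midbrain.

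Several of these differences belonged to some ages or some arrays. The Phgdh probe set was low in both genotypes at 6 weeks (striatum KO 6.13 ± 0.08 and WT 5.93 ± 0.42) and high in WT only from 12 weeks on (striatum 12 weeks KO 5.92 ± 0.17 and WT 10.21 ± 0.58). Its difference varied with age in midbrain (F test, adjusted p = 3.82e-07) and cerebellum (adjusted p = 3.84e-06). Glo1 and Mid1 differed at 6 weeks above all. Glo1 in midbrain was 11.24 ± 0.07 in KO and 10.25 ± 0.02 in WT at 6 weeks and 11.24 ± 0.03 in both at 12 weeks (WT n = 2). Mid1 in cerebellum was 5.77 ± 0.40 and 8.46 ± 0.31 at 6 weeks and 5.75 ± 0.10 and 6.17 ± 0.65 at 12 weeks. These also varied with age (Glo1 adjusted p = 1.41e-05 in midbrain and 7.08e-06 in cerebellum, Mid1 adjusted p = 0.00225 in cerebellum). Tia1 in striatum was 9.64 ± 0.06 in KO and 4.51 ± 0.37 in WT at 6 weeks, and 5.91 ± 2.11 and 4.95 ± 0.20 at 18 months. Only KO replicate 2 stayed high there (8.35, and 8.75 in midbrain and 8.95 in cerebellum). Of some genes a single probe set carried the difference: only 1 of 6 probe sets of Tia1, 1 of 4 of Erc1, and 1 of 3 of Clta and of Mid1 rose or fell so in each region. Of others several did, as 2 of 2 of Cep83os and 2 or 3 of 4 of Srsf10 fell and 2 or 3 of 4 of Glo1 rose. Of Srrm1 2 of 7 rose. Of Phgdh 1 of 4 carried the fall in each region. The others lay at -0.18 to 0.03, and only the striatum value of -0.18 passed. Probe sets of Hnrnpr and Pnrc2 went both ways, with 1 rising and 1 or 2 falling in every region, and 1 further probe set of Tia1 fell in striatum (-0.11).

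**Figure D2:**
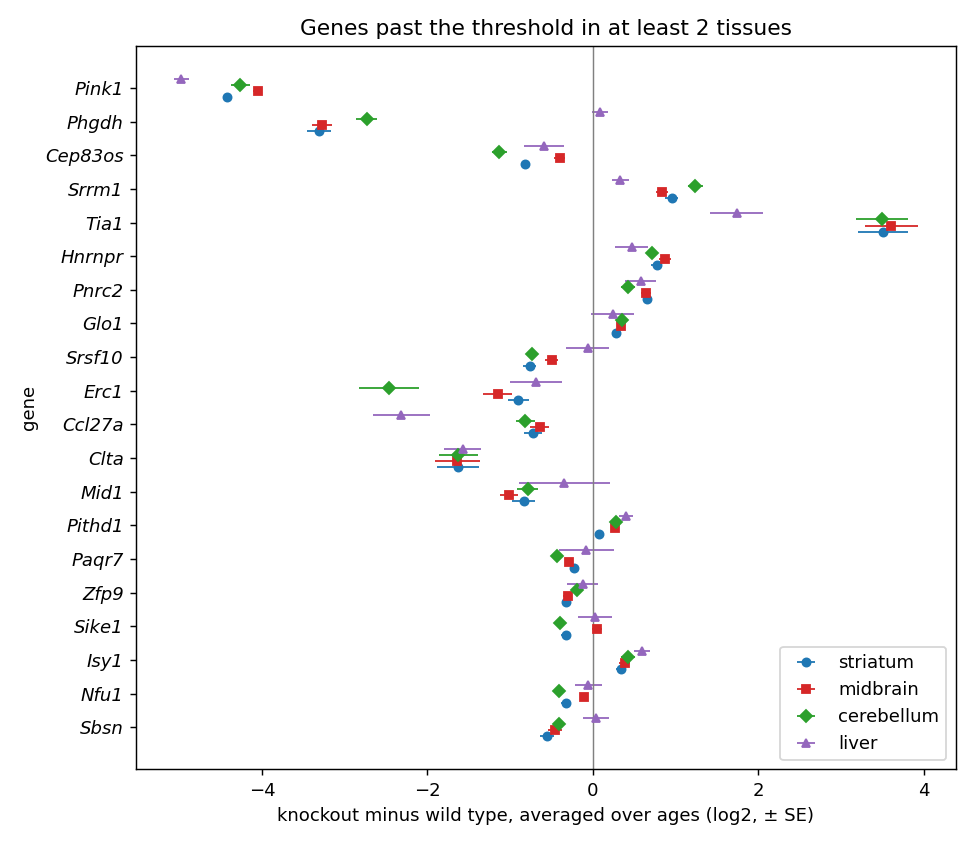
Averaged KO minus WT difference (log2, points, with bars of ± 1 SE) of the 20 genes of smallest p among those that passed in at least 2 tissues, in striatum, midbrain, cerebellum and liver. Tia1 lies at 3.50 to 3.61 in the brain regions and Phgdh at -3.31 to -2.73, while Phgdh in liver lies at 0.08.

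**Figure D3:**
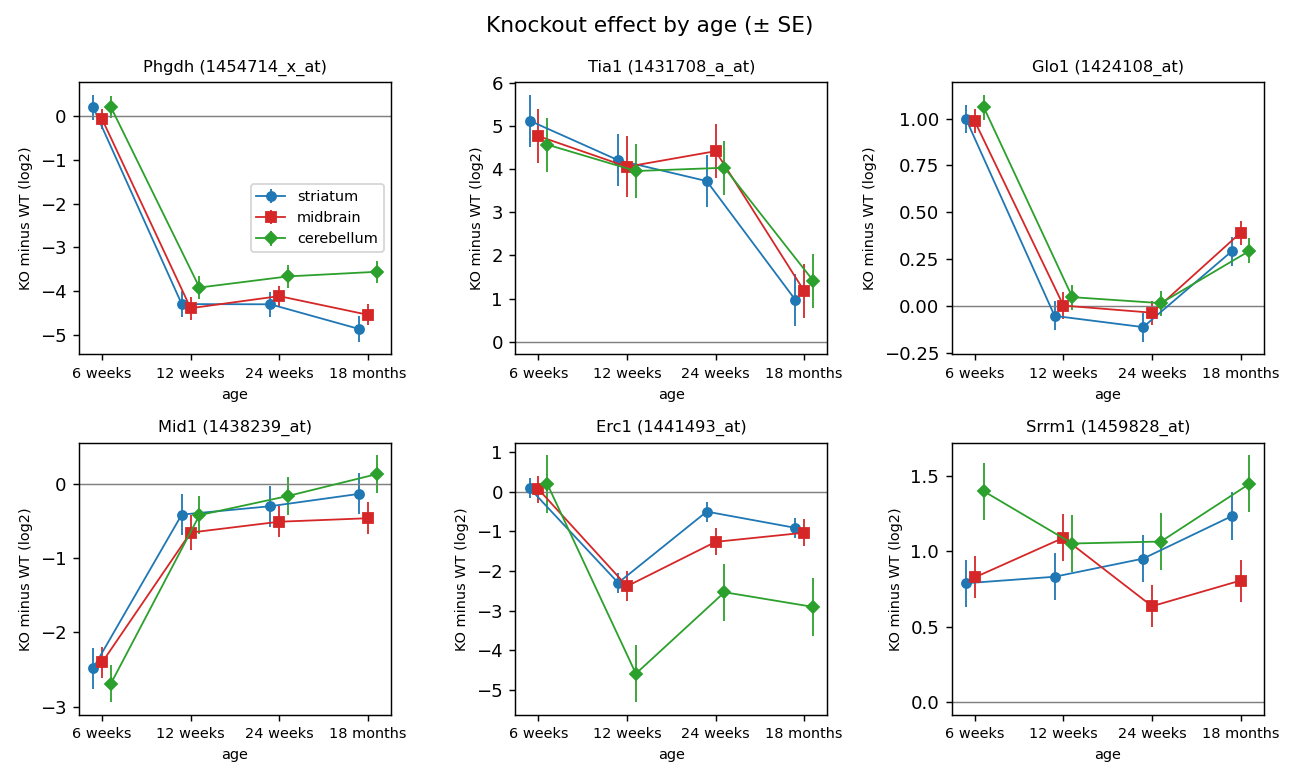
KO minus WT difference (log2, points, with bars of ± 1 SE) at each age for Phgdh, Tia1, Glo1, Mid1, Erc1 and Srrm1 in the 3 brain regions. Phgdh in striatum goes from 0.20 at 6 weeks to -4.29 at 12 weeks, and Glo1 from 1.00 to -0.05.

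The regions shared more calls than independent draws would give. Of the 5037 probe sets of striatum and 55 of midbrain, 43 were shared, 42 of them in the same direction, where 6.15 would be expected for independent sets. Striatum and cerebellum (159 probe sets) shared 94, 93 in the same direction, against 17.78, and midbrain and cerebellum shared 34, all 34 in the same direction, against 0.19. In all 3 regions 32 probe sets passed, all 32 in the same direction, with 17 named genes. All 18-month KO arrays of striatum and cerebellum had a low mean signal, so those 2 regions shared this property of the arrays as well as genotype. Without the 18-month arrays 61 probe sets of striatum, 61 of midbrain and 48 of cerebellum passed. Of these, in an overlap chosen after seeing the data, 29 were shared by striatum and midbrain, 28 by striatum and cerebellum and 27 by midbrain and cerebellum, all in the same direction, against 0.08, 0.07 and 0.07. The labels leave open whether arrays of the same number come from the same animal, which would let regions share more than genotype. The averaged difference varied between regions for 630 probe sets (505 named genes). Those with the smallest p were Dlx6, a transcription factor of forebrain inhibitory neurons (-0.56 in striatum, 0.06 in midbrain and 0.10 in cerebellum, adjusted p = 2.92e-05), Arhgef39 (-0.94, -0.08 and 0.37, adjusted p = 2.92e-05), the hexokinase Hk2 (-0.02, 0.07 and -0.60, adjusted p = 5.71e-04), Cep83os (-0.82, -0.40 and -1.13, adjusted p = 7.98e-04) and Dmkn (-0.82, -0.16 and 0.12, adjusted p = 0.00152). Without the 18-month arrays, an alternative chosen after seeing the data, 12 probe sets passed the region test. That fit treats arrays of the same number in different regions as independent, which the 6-week Xist values below go against. Deviations from the group mean had a median correlation of 0.07 between 2 regions for the same number and -0.04 for other numbers. With a block for the same number across regions, also chosen after seeing the data, the count was 125, and 36 with the planned block for the same number across genotypes. Without midbrain WT 12 weeks replicate 1 the count was 42, and 2537 without cerebellum KO 24 weeks replicate 1.

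In striatum further genes differed on average over ages. Lsm14a, a protein of RNA processing bodies, rose by 0.72 (SE 0.17), 1700010H22Rik by 0.62 (SE 0.06), the actin-severing gelsolin Gsn by 0.61 (SE 0.07) and the protease gene Tmprss2 by 0.54 (SE 0.08). The last 3 lay between 0.01 and 0.27 at 6 to 24 weeks and at 1.53 to 2.09 at 18 months, and Lsm14a lay at 0.70 to 1.28 up to 24 weeks and at 0.07 at 18 months. Only 1 of 4 probe sets of Lsm14a, 1 of 6 of Gsn and 1 of 4 of Tmprss2 passed, and 2 of 3 of 1700010H22Rik. Arhgef39 fell by 0.94 (SE 0.17), the ubiquitin ligase Trim13 by 0.92 (SE 0.20), the tropomyosin Tpm2 by 0.87 (SE 0.16) and Dmkn by 0.82 (SE 0.14), with adjusted p of 3.21e-06 to 0.0135 over these 8 genes. Between 6 and 24 weeks 31 probe sets passed at 6 weeks (18 up, 13 down), 18 at 12 weeks (7 up, 11 down) and 8 at 24 weeks (3 up, 5 down). With 1 array left out these counts ran from 14 to 55, 8 to 132 and 5 to 115, and array weights gave 667 at 12 weeks and 3186 at 24 weeks. Among them were the vascular early response gene Apold1 at 12 weeks (KO 7.31 ± 0.29, WT 6.07 ± 0.23, log2 difference 1.24, SE 0.19, adjusted p = 0.00903), Depp1 at 12 weeks (0.99) and the co-chaperone Bag2 at 24 weeks (KO 5.57 ± 0.11, WT 6.33 ± 0.21, adjusted p = 0.0433). Pink1 apart, largest at 6 weeks, besides Tia1 (5.13) and Mid1 (-2.48), were Glo1 (1.10), Hnrnpr (1.08) and Cep83os (-1.02), and Phgdh fell most at 12 (-4.29) and 24 weeks (-4.30), followed by Erc1 at 12 weeks (-2.30).

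At 18 months 11715 probe sets differed between the genotypes in striatum (3836 up, 7879 down). Cped1 rose most (KO 6.78 ± 0.13, WT 3.94 ± 0.23, log2 difference 2.83, SE 0.12, adjusted p = 1.22e-12), followed by Bpifb1 (8.38 ± 0.05 and 5.81 ± 0.12) and the RNA helicase Ddx54 (7.17 ± 0.38 and 4.86 ± 0.15). Besides Phgdh (-4.86) and Pink1, Cxcl13, a chemokine that attracts B cells, fell most (4.89 ± 0.22 and 7.71 ± 1.92, log2 difference -2.82, adjusted p = 6.45e-04). The difference varied with age for 3688 probe sets by the F test, with the smallest p for Cped1 (2.63e-10 adjusted), Bpifb1 (9.54e-10), Acer3 (1.41e-09), Sf1 (1.11e-08) and Zfp3 (3.34e-08). All 5 lay close to 0 at 6 to 24 weeks (-0.38 to 0.17) and at 1.82 to 2.83 at 18 months. The difference at 18 months exceeded or fell short of that at 6 weeks for 5030 probe sets (1714 up, 3316 down). All 3 KO arrays of this group had a mean signal of 6.40 to 6.41, under every WT array of the group and every brain array of 6 to 24 weeks, and the median difference over all probe sets was -0.10. With quantile normalization 6880 probe sets passed, 4068 up and 2812 down, and 3052 for the comparison with 6 weeks (2076 up, 976 down). With a filter at the median signal 7209 passed, 620 up and 6589 down. The direction of the majority thus depended on the scaling. The averaged count of 5037 (1892 up, 3145 down) was 2358 with quantile normalization (1349 up, 1009 down) and 61 without the 18-month arrays.

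Of the 35 gene lists, 10 shifted between the genotypes in striatum on average over ages, 8 down and 2 up, each with an adjusted p of 0.69 with an estimated correlation. Single members were called in the average, whose count fell from 5037 to 61 without the 18-month arrays. At 18 months all KO arrays had a low mean, so younger ages may differ. The mitochondrial ribosome shifted down (adjusted p = 7.98e-04). Of its 28 measured members 6 fell, 22 did not pass and, adjusted over the list alone, 10 fell, with Mrps22 at -0.22, Mrpl16 at -0.18, Mrps10 at -0.16 and Mrps2 at -0.14. Heat shock and chaperone genes shifted down (adjusted p = 0.00753), with 9 of 23 fallen over all genes and 9 adjusted over the list alone, among them the inducible Hsp70 genes Hspa1b (-0.49) and Hspa1a (-0.43), Dnajb1 (-0.24) and Ahsa1 (-0.18). Respiratory complex I (adjusted p = 0.00832, Ndufs4 -0.15, 1 of 33 fallen), complexes II to IV (0.0489, 0 of 23), mitochondrial import (0.03, Htra2 -0.21, 1 of 27), the proteasome (0.00816, Psma2 -0.14 and Psmc6 -0.13, 2 of 28) and the cytosolic ribosome (0.0211, Rpl14 -0.26, 1 of 28) shifted down with few members past the threshold. Adjusted over the list alone, these 5 lists had 0, 0, 1, 2 and 0 fallen members. Astrocyte markers shifted down (0.0489), with 4 of 14 fallen and 5 adjusted over the list alone, namely Slc14a1 (-0.34), Aldh1l1 (-0.23), Aqp4 (-0.20) and Acsbg1 (-0.19). Endothelial markers shifted up (0.00832), where Slco1a4 (0.16) and Acta2 (0.16) rose, also adjusted over the list alone. Markers of medium spiny neurons shifted up (0.0493), although their only member past the threshold, the opioid precursor Pdyn, fell (KO 8.14 ± 0.04, WT 8.47 ± 0.13 at 6 weeks, averaged difference -0.23). Among dopaminergic markers, whose list did not shift (0.519), the vesicular monoamine transporter Slc18a2 fell (-0.52) and the nicotinic receptor subunit Chrna6 rose (0.26). Microglia genes (0.157) and regulators of mitochondrial biogenesis (0.398) did not shift, while Aif1 (-0.32), Tyrobp (-0.29), Tfb1m (-0.29) and the mitochondrial transcription factor Tfam (-0.26) fell and Esrrb rose (0.37). Cholesterol synthesis genes did not shift as a list (0.0628) while 5 of 21 fell, among them Idi1 (-0.24), Cyp51 (-0.23), Sc5d (-0.20) and Me1 (-0.20).

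In midbrain the cartilage factor Cnmd rose by 1.16 (SE 0.18, adjusted p = 0.00648), Lsm14a by 0.66, the synaptic pentraxin Nptx2 by 0.65 (SE 0.12, adjusted p = 0.0162) and Garre1 by 0.55, while Pigo, of the synthesis of membrane anchors, fell by 0.48. The average over ages had 55 probe sets past the threshold (28 up, 27 down). At 6 weeks 27 probe sets passed (12 up, 15 down), among them Foxp1, a transcription factor of neurons (KO 4.59 ± 0.18, WT 6.68 ± 0.07, log2 difference -2.09, SE 0.26, adjusted p = 6.21e-04), and Pnrc2 (1.15). At 12 weeks 8 passed (3 up, 5 down), with Srrm1 (1.09), Pnrc2 (0.87), Phgdh (-4.38) and Erc1 (-2.38). At 18 months 12 passed (5 up, 7 down), with Hnrnpr (1.16), Srrm1 (0.81), Glo1 (0.39) and, downward, Phgdh (-4.54) and Anxa9 (KO 4.86 ± 0.22, WT 5.56 ± 0.03). Only 6 probe sets (2 up, 4 down) differed between 18 months and 6 weeks in their KO minus WT difference.

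At 24 weeks 2845 probe sets differed in midbrain (1922 up, 923 down). Slc12a5, the potassium and chloride cotransporter of mature neurons, was 9.90 ± 0.22 in KO and 7.25 ± 0.62 in WT (log2 difference 2.65, SE 0.20, adjusted p = 2.21e-07), against WT levels of 9.63 to 9.98 at the other ages. The transcription factor Nfic was 7.27 ± 0.46 and 4.78 ± 0.53 (difference 2.48, SE 0.23, adjusted p = 2.27e-06), Hspa4, a chaperone of the Hsp70 family, 9.49 ± 0.05 and 8.44 ± 0.10, and the chromatin insulator protein Ctcf 8.83 ± 0.16 and 7.80 ± 0.10. The inducible Hsp70 gene Hspa1b fell (7.08 ± 0.54 and 8.96 ± 1.10, difference -1.88, SE 0.40, adjusted p = 0.00765), as did Phgdh (-4.11). The difference varied with age for 742 probe sets (569 named genes), with Phgdh, Glo1, Hspa4 (adjusted p = 2.62e-05), Slc12a5 (2.64e-05) and Ctcf (3.49e-05) at the smallest p. Slc12a5, Hspa4 and Ctcf lay within -0.31 to -0.01 at 6 weeks, 12 weeks and 18 months. At 24 weeks the Gapdh 3' minus 5' control difference was -0.01 ± 0.03 in KO and 0.12 ± 0.09 in WT. With that difference as a covariate the count was 842, as the median SE of the called probe sets grew from 0.11 to 0.15 while their median difference was 0.48 and 0.49. Without WT replicate 1 the count was 1144 and without KO replicate 3 it was 5231. The count of the F test was 214 and 1673 without the same 2 arrays.

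**Figure D4:**
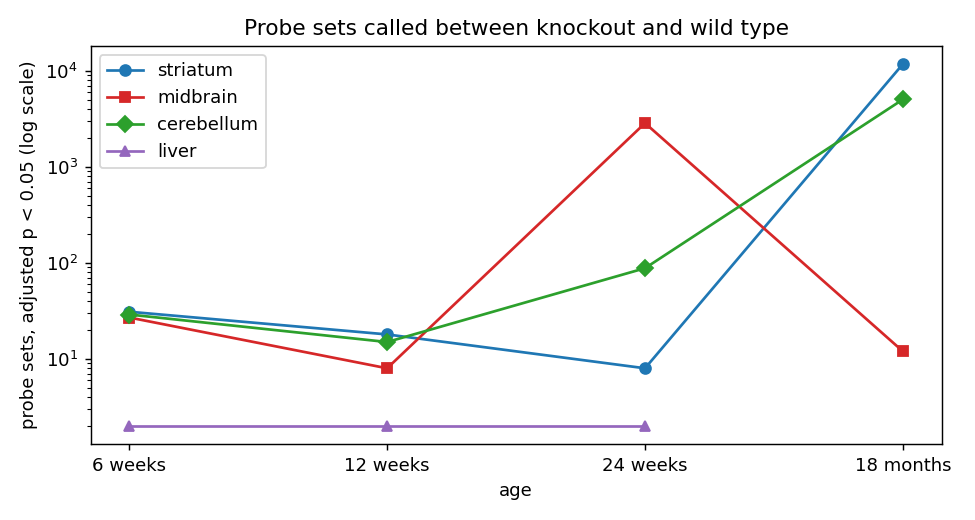
Number of probe sets past the threshold between KO and WT at each age (log scale) in striatum, midbrain, cerebellum and liver. The largest counts are 11715 in striatum and 5020 in cerebellum at 18 months and 2845 in midbrain at 24 weeks, and liver has 2 at each age.

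In midbrain 5 lists shifted between the genotypes on average, and none kept the call with an estimated correlation (adjusted p = 0.646 to 0.798). Interferon response (adjusted p = 0.0105), microglia (0.0115), mitochondrial ribosome (0.0115) and proteasome genes (0.0211) shifted up and heat shock genes (0.0211) shifted down, with 0 members of each past the threshold over all genes. Adjusted over the list alone, 3 of 21 microglia genes rose, the lysosomal protease Ctss (0.22) and the complement genes C1qa (0.22) and C1qb (0.23), while the other 4 lists had 0. The astrocyte gene Aldh1l1 fell (-0.21) and the clock gene Cry2 rose (0.52), in lists that did not shift (0.161 and 0.433). The dopaminergic list did not shift (0.362), with the tyrosine hydroxylase gene Th at 0.09 (SE 0.06, adjusted p = 0.929) and Slc18a2 at 0.07.

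In cerebellum Cnmd rose by 1.25 (SE 0.25, adjusted p = 0.0339), Lsm14a by 0.57 and Pi4kb, a lipid kinase of the Golgi, by 0.43 (SE 0.08, adjusted p = 0.0246). Trim13 fell by 0.93 (SE 0.20, adjusted p = 0.0447), Zfand5 by 0.69 (SE 0.15, and -1.76 at 18 months) and the second Pnrc2 probe set by 0.87. The averaged difference passed for 159 probe sets (51 up, 108 down), for 48 without the 18-month arrays, for 53 without KO 6 weeks replicate 1 and for 2201 without WT 24 weeks replicate 1. At 6 weeks 29 probe sets passed (14 up, 15 down), led by Tia1 (4.58), Srrm1 (1.40), Glo1 (1.06), Mid1 (-2.69) and Ccl27a (-1.43). At 12 weeks 15 passed (7 up, 8 down), with Erc1 at 4.92 ± 0.15 in KO and 9.52 ± 0.07 in WT and Apold1 at 6.99 ± 0.40 and 5.73 ± 0.13. At 24 weeks 88 passed (50 up, 38 down), among them the RNA polymerase subunit Polr2a (KO 9.59 ± 0.34, WT 8.22 ± 0.77, adjusted p = 0.0361), Rnf208 (10.85 ± 0.23 and 9.70 ± 0.61) and, downward, the kinase gene Sgk1 (9.85 ± 0.22 and 10.97 ± 0.22, adjusted p = 0.00544). That 24-week count was 5 without WT replicate 2 and 3038 without WT replicate 1.

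At 18 months 5020 probe sets differed in cerebellum (1236 up, 3784 down). The potassium channel subunit Kcne2, abundant in choroid plexus, was 7.38 ± 0.17 in KO and 5.71 ± 1.12 in WT (difference 1.67, SE 0.40, adjusted p = 0.00992). Ddx54 rose by 1.58 and the immunoglobulin gene Igha by 1.57 (7.74 ± 1.25 and 6.17 ± 0.56). Erc1 (-2.91) and Phgdh (-3.56) fell. The difference varied with age for 134 probe sets, with Phgdh, Glo1, Mid1, Sgk1 (adjusted p = 0.0044) and the RNA helicase Ddx5 (-0.96 at 18 months and 0.02 to 0.18 before, adjusted p = 0.00635) at the smallest p. The difference at 18 months departed from the one at 6 weeks for 57 (15 up, 42 down). Without WT 18 months replicate 1 these counts were 2800 and 2670, without WT 24 weeks replicate 2 the first was 9, and without WT 18 months replicate 2 the second was 4. The 3 KO arrays and WT replicate 1 of this group had the low mean signals (6.41 to 6.43). The Gapdh 3' minus 5' control difference was 0.64 ± 0.31 in KO and 0.09 ± 0.03 in WT. The median difference in the calls' direction was 0.35 for KO minus WT replicate 1 and 0.61 for KO minus replicates 2 and 3. WT replicate 1 minus replicates 2 and 3 gave 0.24. A block for low array mean, chosen after seeing the data, rests on WT replicate 1 at 18 months. With the Gapdh covariate, which followed genotype, the 18-month count was 25. It was 1397 without KO replicate 3 and 8921 without WT replicate 1.

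**Figure D5:**
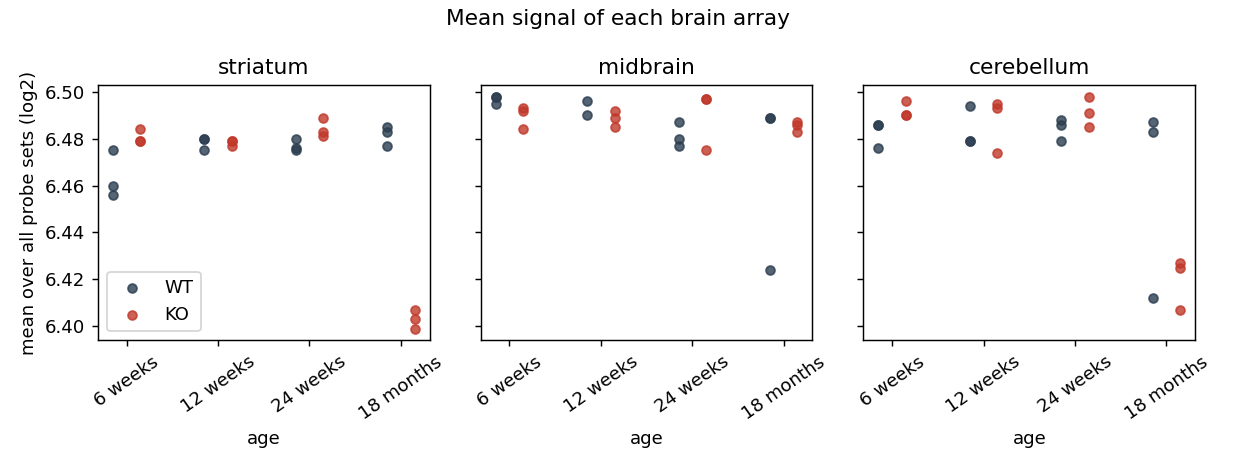
Mean log2 signal over all probe sets of each brain array by age, with WT and KO arrays as points. At 18 months 8 arrays lie between 6.40 and 6.43, the 3 KO arrays of striatum and of cerebellum, 1 WT array of cerebellum and 1 of midbrain, and the other 10 lie between 6.48 and 6.49.

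Of the 35 lists, 12 shifted in cerebellum on average, 10 down and 2 up, and none kept the call with an estimated correlation (adjusted p = 0.432 to 0.518). The average included 18 months, where the Gapdh control difference was 0.64 ± 0.31 in KO and 0.09 ± 0.03 in WT. There 3 KO and 1 WT array had a low mean. Mitochondrial lists shifted down, with 0 members of any of them past the threshold over all genes. These were complex I (adjusted p = 1.08e-05, with 7 of 33 fallen adjusted over the list alone, Ndufb5 at -0.16), complexes II to IV (6.31e-04, 0 of 23), ATP synthase (6.13e-04, 2 of 16), the citric acid cycle (0.00261, 4 of 16, Idh3a at -0.19), import (0.00214, 1 of 27, Timm17a at -0.22) and the mitochondrial ribosome (2.07e-05, 1 of 28, Mrps2 at -0.17). Parkinson disease genes shifted down (0.0288), with 2 of 14 fallen adjusted over the list alone, Vps35 at -0.14 and Lrrk2 at -0.15. Proteasome genes (7.61e-06, 7 of 28 fallen adjusted over the list alone), heat shock genes (1.13e-05, 12 of 23 fallen and 1 risen so, Dnajb1 at -0.29 and Cryab at -0.23) and cholesterol synthesis genes (0.00382, 1 of 21, Fdps at -0.29) shifted down as well. Endothelial markers (0.00394, Slco1a4 at 0.19, 1 of 16 risen adjusted over the list alone) and interferon response genes (0.00221, 0 of 22, Cd74 at 0.40) shifted up. Outside these lists Hk2 fell (KO 7.64 ± 0.06 and WT 8.45 ± 0.05 at 6 weeks, averaged difference -0.60, SE 0.07, adjusted p = 1.05e-04), as did the clock gene Arntl (-0.19) and the glutathione synthesis gene Gclm (-0.18).

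The brain lists that did not shift between the genotypes in any region were those of mitochondrial biogenesis, mitophagy, dopaminergic and serotonergic neurons, Purkinje and granule cells, oligodendrocytes, blood, choroid plexus, cortical neurons, thalamus and hypothalamus, pituitary, synaptic vesicles, immediate early genes, circadian clock, integrated stress response, antioxidant genes, glycolysis and sex chromosome genes. Lists past no threshold had adjusted p of 0.0513 to 0.98 in striatum, 0.0792 to 0.915 in midbrain and 0.11 to 0.983 in cerebellum. Median, mean and test differed in sign only in lists that did not shift, 6 in striatum, 9 in midbrain and 6 in cerebellum, such as dopaminergic markers in striatum (median 0.001, mean -0.02, test up).

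In liver only Anxa4, which binds membranes in the presence of calcium, rose besides the fall of Pink1. Anxa4 was 9.71 ± 0.12 in KO and 8.94 ± 0.05 in WT at 6 weeks and rose by 0.52 on average (SE 0.07, adjusted p = 0.0272). Of its 3 probe sets 1 rose, while in striatum and cerebellum 1 probe set of the gene fell. Clta (-1.57, SE 0.22, adjusted p = 0.0682), Ccl27a (-2.32, SE 0.35, adjusted p = 0.0929), Isy1 (0.59, SE 0.10, adjusted p = 0.166) and Tia1 (1.74, SE 0.32, adjusted p = 0.465) lay on the same side as in brain without passing, and Phgdh lay at 0.08 (SE 0.10). Averaged over ages 4 probe sets passed (1 up, 3 down), and at each of the 3 ages only the 2 Pink1 probe sets did. No probe set passed the F test over ages with limma (0, and 2153 at an unadjusted p under 0.05), where the smallest adjusted p was 0.8 for Slc8a1, Socs2, Irgm2, Ctcflos and Hipk2. Without WT 12 weeks replicate 1 the averaged count was 2. Without KO 24 weeks replicate 2, whose Gapdh 3' minus 5' control difference was 4.833, it was 13. Without KO replicate 3 the 24-week count was 1259.

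Of the 28 liver lists, 5 shifted between the genotypes, and none kept the call with an estimated correlation (adjusted p = 0.489 to 0.904). Cytosolic ribosome (adjusted p = 0.0014, median difference 0.12) and immediate early genes (0.00684, Egr1 at 0.95 and Jun at 0.47) shifted up. Acute phase genes (0.0014, Saa1 at -0.99 and Serpina3n at -0.37), cholesterol synthesis genes (0.00684, Dhcr7 at -0.50 and Lss at -0.39) and genes of zonation and gluconeogenesis (0.0143, Ass1 at -0.56 and Pck1 at -0.37) shifted down. In none of these lists did a member pass, over all genes or adjusted over the list alone. The other 23 liver lists, those of fatty acid oxidation (0.659), bile acid and xenobiotic metabolism (0.309) and sex-dimorphic genes (0.101) among them, had adjusted p of 0.0593 to 0.912, and 5 of them had a median, mean and test of different sign.

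The 6-week arrays, to which every age was compared, differed from the 12-week ones in sex-linked genes in both genotypes (genes chosen after their values were seen). In striatum Xist was 2.00 log2 lower at 12 weeks in WT and 2.13 lower in KO, and Eif2s3y was 1.63 and 1.73 higher. Midbrain and cerebellum changed likewise, Xist by -2.11 and -2.20 in WT. With the Xist covariate the 24-week age count was 2232 in midbrain (4365 without it) and 582 in cerebellum (1605 without it). In WT and not in KO, Fos, Nr4a3 and Hspa1b fell over 2-fold from 6 to 12 weeks in every brain region. Age falls of immediate early genes below include this 6-week WT difference. The 18-month arrays also differed in preparation. The labelling control Dap had means of 12.65 to 12.81 there against 9.49 to 10.54 at 6 to 24 weeks. Every 18-month age effect and list shift below includes this difference.

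In striatum the nuclear RNA Malat1 rose by 2.99 log2 between 6 weeks and 18 months (SE 0.28, adjusted p = 7.55e-08), together with Akap9 (3.00), Hnrnpab (2.66), the synaptic priming protein Unc13c (2.54) and the chromatin remodeller Atrx (2.47). The immediate early genes Egr2 (-3.002) and Fos (-2.34, from 10.10 ± 0.28 to 7.70 ± 0.84 in WT), Neurod6 (-2.46) and the liver-made proteins Serpina1c (-3.67) and Alb (-2.70) fell most. Serpina1c and Alb were uneven between arrays at 6 weeks (KO 7.92 ± 2.03 and 6.71 ± 2.07). At 18 months 18100 probe sets passed (6892 up, 11208 down), and 8111 without the low-mean arrays (4456 up, 3655 down), which leaves WT arrays alone at 18 months. With WT arrays alone at all ages it was 6384 (3709 up, 2675 down), so the direction of the majority depended on the arrays. At 24 weeks 5135 passed (2535 up, 2600 down). Phgdh (2.27), Ddx6 (1.40), Malat1 (1.31), Snhg11 (1.30) and Smg1 (1.23) rose most and Serpina1c (-2.57), Alb (-2.57), Serpina1b (-1.92), Fabp1 (-1.82) and the cyclin Ccnd2 (-1.48) fell most. Phgdh rose there through the WT arrays, as its KO levels were 6.13 and 6.15.

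Of the 35 lists, 5 shifted with age in striatum at 18 months, each with an adjusted p of 0.816 with an estimated correlation. Immediate early genes shifted down (adjusted p = 0.00107), with 16 of 20 fallen over all genes and adjusted over the list alone, among them Jun (-1.02) and Egr4 (-0.96). Complexes II to IV (12 of 23 fallen, 13 adjusted over the list alone, Cox8a -0.51), ATP synthase (11 and 12 of 16, Atp5g1 -0.55) and mitochondrial import (12 and 13 of 27, Tomm22 -0.31) shifted down (each 0.0475). Interferon response genes shifted up (0.0475, 6 risen and 2 fallen of 22, 5 and 2 adjusted over the list alone), with the antigen presentation genes Cd74 (0.97) and H2-Ab1 (0.57). The astrocyte filament gene Gfap rose (0.91, SE 0.15, adjusted p = 1.09e-04) in a list that did not shift (0.22).

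In midbrain Akap9 (2.01, SE 0.13, adjusted p = 2.35e-09), Phgdh (1.94), the potassium channel Kcnma1 (1.74), the lipid transporter Abca8a (1.59) and Unc13c (1.59) rose most between 6 weeks and 18 months. Growth hormone, Gh, fell by 2.15 (SE 0.79, adjusted p = 0.0472), with 7.55 ± 4.20 in KO and 4.36 ± 0.22 in WT at 6 weeks, followed by Gm5113 (-1.78), 9630013A20Rik (-1.77), Rgs16 (-1.62) and Taf15 (-1.54). The count was 12780 (5458 up, 7322 down). The Gapdh control difference followed age here (-0.10 in KO and -0.09 in WT at 6 weeks, 0.19 in both at 18 months), so the count of 38 with it as a covariate says little on age. With KO arrays alone, chosen after seeing the data, Phgdh at 18 months lay at -0.30 (adjusted p = 0.335). At 24 weeks 4365 probe sets passed (1876 up, 2489 down), with Phgdh (2.23), Abca8a (1.29), Erc1 (1.20), Gm4349 (1.14) and Rragd (0.95) rising and the postsynaptic scaffold Dlg4 (-1.66), Mid1 (-1.35), Atp6v0a1 (-1.30), 9630013A20Rik (-1.29) and Slc12a5 (-1.25) falling most. In this fit 6961 passed within WT and 77 within KO, and with KO arrays alone in the fit the count was 8 and Slc12a5 lay at 0.23 (adjusted p = 0.535). Dlg4 in WT was 9.14 ± 0.26 at 6 weeks and 6.22 ± 0.24 at 24 weeks, and in KO 8.91 ± 0.31 and 8.52 ± 0.23.

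In all, 11 lists shifted with age in midbrain at 18 months (adjusted p = 0.37 to 0.542 with an estimated correlation). Immediate early genes shifted down most (2.06e-05, 15 fallen and 1 risen of 20, 16 and 1 adjusted over the list alone), with Npas4 (-1.18), Dusp1 (-1.06), Btg2 (-1.02) and Jun (-0.80). Myelin genes shifted down (0.00104, 10 fallen and 1 risen of 16, 11 and 1 adjusted over the list alone), with Opalin (-0.76), Mal (-0.55) and Ugt8a (-0.48). Complex I, complexes II to IV and ATP synthase (each 9.32e-04, with 15 of 33, 12 of 23 and 10 of 16 fallen, and 16, 13 and 11 adjusted over the list alone) also shifted down, with Ndufa8 (-0.40), Cox8a (-0.42) and Atp5g1 (-0.49). So did the mitochondrial ribosome (0.00118, 13 of 28, 16 adjusted over the list alone), the proteasome (0.00175, 12 of 28, 13), Parkinson disease genes (0.0327, 7 of 14, 7) and cholesterol synthesis (0.00104, 11 of 21, 12, Fdps -0.74). In each of these lists, and in complexes II to IV, 1 member rose. Synaptic vesicle genes (0.00159, 8 risen and 1 fallen of 18, 8 and 2 adjusted over the list alone, Syn2 0.56 and Gad2 0.48) and medium spiny neuron markers (0.0126, 8 risen and 1 fallen of 16, Drd2 0.47) shifted up. Gfap rose by 1.02 in an astrocyte list that did not shift (0.093).

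In cerebellum the cohesin acetyltransferase Esco1 rose by 3.00 between 6 weeks and 18 months (SE 0.23, adjusted p = 3.11e-09), with Atrx (2.77), Smg1 (2.72), Pnmal2 (2.63) and Rb1cc1 (2.49). Fos (-2.84), Nr4a2 (-2.52), Mkrn3 (-2.52, SE 0.13, adjusted p = 2.95e-11), Fosl2 (-2.26) and Taf15 (-1.89) fell most. Mkrn3 in WT fell from 6.28 ± 0.13 at 6 weeks to 4.49 ± 0.43 at 12 weeks and 3.85 ± 0.14 at 18 months. The count was 19282 (6559 up, 12723 down), and 8719 without the low-mean arrays (4447 up, 4272 down), with WT arrays alone at 18 months. With WT arrays alone at all ages it was 10827 (4388 up, 6439 down). At 24 weeks 1605 passed (816 up, 789 down), with Erc1 (2.90), Dlg4 (1.92), Arf3 (1.72), Phgdh (1.66) and Nfic (1.65) rising and Mkrn3 (-1.89), Mid1 (-1.59), Zbtb16 (-1.30), Mybpc3 (-1.15) and the myelin claudin Cldn11 (-1.11) falling most. That count was 619 without WT 24 weeks replicate 2, 4122 without replicate 1, and 27 with KO arrays alone, where Phgdh lay at -0.28 (adjusted p = 0.442). Mid1 fell and Erc1 rose mainly in WT here and in midbrain. KO Mid1 was 5.45 to 6.22 at 6 weeks and 5.21 to 5.57 at 24 weeks. Only KO replicate 3 had high Erc1 at 24 weeks (9.59, others 4.71 and 5.44).

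In all, 8 lists shifted with age in cerebellum at 18 months (adjusted p = 0.475 to 0.921 with an estimated correlation). Complex I (1.78e-04, 27 of 33 fallen), complexes II to IV (4.45e-05, 19 of 23), ATP synthase (5.96e-04, 11 of 16) and the mitochondrial ribosome (0.0332, 21 of 28) shifted down, with Cox8a (-0.92), Atp5g1 (-0.84), Ndufa7 (-0.68) and Mrpl15 (-0.49), and 27, 19, 12 and 22 fallen adjusted over the list alone. In complex I, complexes II to IV and the mitochondrial ribosome 1 member each rose. Myelin genes (2.27e-04, 12 of 16 fallen, 12 adjusted over the list alone), cholesterol synthesis (4.45e-05, 17 of 21, 17) and immediate early genes (0.00644, 16 of 20, 17) shifted down too, with Opalin (-1.07), Fa2h (-0.85), Sqle (-0.96) and Btg2 (-1.11). Microglia genes shifted up (5.93e-05, 8 risen and 1 fallen of 21, 8 and 1 adjusted over the list alone), with C1qa (0.88), Cx3cr1 (0.74) and Ctss (0.65) risen and Tmem119 (-0.58) fallen. Lists that did not shift with age had adjusted p of 0.0515 to 0.908 in striatum, 0.0705 to 0.832 in midbrain and 0.0644 to 0.991 in cerebellum. Among these, median, mean and test differed in sign in 5, 4 and 12 lists. In cerebellum all 12 had a median under 0 and a test up, as the test sets a list against the other genes.

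In liver no gene passed between 6 and 24 weeks. The Gapdh 3' minus 5' control difference was 0.98 ± 1.04 in WT at 6 weeks and 1.86 ± 2.57 in KO at 24 weeks, against 0.11 to 0.18 in the other groups. With limma 0 probe sets passed and 3556 had an unadjusted p under 0.05. Of the 28 lists, 13 shifted, 9 down and 4 up, with adjusted p of 0.104 to 0.628 with an estimated correlation. Complex I shifted down (adjusted p = 5.67e-17), with 13 of 33 fallen adjusted over the list alone, such as Ndufb8 (-0.47, SE 0.10), Ndufv1 (-0.45) and Ndufs7 (-0.34). Complexes II to IV (9.55e-12, 4 of 23 so), ATP synthase (1.06e-08, 5 of 16), the citric acid cycle (4.8e-05, 1 of 16), the mitochondrial ribosome (0.00496, 0 of 28) and mitochondrial biogenesis (0.0173, 2 of 16) shifted down as well, with the coactivator Ppargc1a at -2.01 (adjusted p = 0.211 over all genes). Fatty acid oxidation (1.71e-06, 2 of 21, Cyp4a14 at -3.08), zonation and gluconeogenesis (1.71e-06, 4 of 16, Rhbg at -0.92) and endothelial genes (0.0491, 0 of 16) shifted down. Heat shock genes (0.00496, 1 of 23 risen, Hspb1 at 1.03), the cytosolic ribosome (0.00184, 0 of 28), blood genes (0.0109, 0 of 7, S100a8 at 1.52) and the proteasome (0.0344, 0 of 28) shifted up. The other 15 lists had adjusted p of 0.0538 to 0.989, and in 2 of them median, mean and test differed in sign. The count of 0 was 217 with the Gapdh covariate, and leaving out KO 24 weeks replicate 1 gave 693.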

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

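The rule for values that differed between groups was set before the results, and the reasons given here were written after they were seen. Between the ages, the difference between KO and WT varied for 3688 probe sets in striatum, 742 in midbrain and 134 in cerebellum, and at 18 months it differed from that at 6 weeks for 5030, 6 and 57. Between the brain regions the averaged difference varied for 630. In striatum the smallest adjusted p belonged to Cped1 (2.63e-10), Bpifb1 (9.54e-10), Acer3 (1.41e-09), Sf1 (1.11e-08) and Zfp3 (3.34e-08), which changed at 18 months alone, where all 3 KO arrays had a low mean signal. In midbrain Phgdh (3.82e-07) had no difference at 6 weeks, Glo1 (1.41e-05) differed at 6 weeks above all, and Hspa4 (2.62e-05), Slc12a5 (2.64e-05) and Ctcf (3.49e-05) differed at 24 weeks alone. In cerebellum Phgdh (3.84e-06), Glo1 (7.08e-06) and Mid1 (0.00225) followed the same course, Sgk1 (0.0044) changed sign between ages and Ddx5 (0.00635) fell at 18 months. Between regions Dlx6 (2.92e-05) and Dmkn (0.00152) fell in striatum above all, Arhgef39 (2.92e-05) fell in striatum and rose in cerebellum, Hk2 (5.71e-04) fell in cerebellum alone, and Cep83os (7.98e-04) fell least in midbrain.

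Control probe sets that no comparison used also stood out. Dap, a transcript added to the RNA before labelling, read higher at 18 months than at 6 to 24 weeks by 3.12 log2 in cerebellum, 2.22 in midbrain and 2.79 in striatum, so the 18-month arrays differ from the younger ones in preparation as well as in age. On the array of liver KO 24 weeks replicate 2 the Gapdh 3' probe set exceeded the 5' one by 4.833 log2, while the other groups of liver had means of 0.11 to 0.98. Most groups hold 3 arrays, and groups of 3 arrays were not tested for a far sample.

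The first weighed pattern is the large counts at single ages. Its tests on arrays of low mean, on genotype alone, on genotype on top of array mean and on the technical axis as the whole cause were chosen after the counts were seen, while the reading of the other 3 was written before their values were. Of the 18-month calls 94.2 percent in striatum and 87.6 percent in cerebellum went the same way in midbrain WT replicate 3, an array of low mean, against WT replicates 1 and 2, so a difference between arrays of low and higher mean is a candidate explanation for both, although it rests on that 1 array. An effect of genotype shared by the regions stayed open (63.3 percent went the same way in midbrain KO against WT replicates 1 and 2). In cerebellum genotype alone (88.5 percent went the knockout's way in WT replicate 1 against 2 and 3) and genotype on top of the array difference (ratio 1.48) stayed open too. The rules first written would have read these values as going against the former and with the latter, and were reworded after the values were seen, because only 1 WT array of low mean exists. For midbrain at 24 weeks a technical axis as the whole cause was argued against, as 69 percent of the calls stayed with it as a covariate (median difference 0.48 before and after, SE 0.11 and 0.12), while a part in the pattern stayed open (70.5 percent of calls on its side). RNA degradation stayed open (842 calls with the Gapdh covariate). With that covariate the median difference was 0.49 and its SE grew from 0.11 to 0.15, which ended most calls.

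The second pattern is that genes called in at least 2 brain regions lie close together on chromosomes, which was noticed in these data and tested on them. Of the 200 genes nearest to Pink1, 6 were called (Paqr7, Srrm1, Srsf10, Pnrc2, Pithd1 and Hnrnpr), 3 percent against 0.35 percent of other genes (Fisher's exact test, 1-sided p = 1.16e-04), and a chromosome segment carried along with the targeted allele is a candidate explanation. Of the 63 called genes elsewhere, 20 had another called gene within 20 genes, where 10000 random sets had a median of 8 and a highest value of 22 (share of sets with as many 0.002). These lay in groups such as Ccl27a, Pigo, Arhgef39, Creb3 and Clta on chromosome 4, Tia1, Nfu1 and Isy1 and also Zfp9 and Erc1 on chromosome 6, and Phgdh, Gdap2, Man1a2 and Sike1 on chromosome 3. Other segments that differ between KO and WT animals may account for them, and as several of these differences sat on 1 probe set of a gene, sequence variants under the probes may as well, which was not tested.

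The third pattern is that 6-week WT arrays stand apart, with tests chosen after it was seen. In every brain region 25 probe sets of WT and 10 of KO changed over 2-fold between 6 and 12 weeks. A difference in background of the 6-week wild types may underlie the 6-week differences of Glo1 and Mid1. This stayed open, as both counts hold sex-linked probe sets (in KO 4 of the 10, of Xist, Eif2s3y and Kdm5d) and cannot decide it. No other named gene was among the 10, while WT also had Phgdh, Erc1, Mid1, Clta, Fut9, Fos, Nr4a3 and Hspa1b. In liver WT 6 weeks replicate 1 had Glo1 at 12.53 and Mid1 at 4.04 and WT 12 weeks replicate 1 had 11.29 and 6.86, each nearer to the other age. An exchange of these 2 arrays stayed open, with 63.6 percent of 11 panel probe sets nearer to the other age for the first and 72.7 percent for the second.

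The splits of arrays into other groups were planned before the results, and a value of 1 means that only the real split reached its own count. With 3 arrays against 3 the 10 splits are too few to weigh, and the real and highest other counts were 31 and 159 (value 2), 18 and 1, 8 and 1, and 11715 and 1 (value 1 each) in striatum at 6, 12 and 24 weeks and 18 months. They were 27 and 1, 2845 and 3, and 12 and 1 (value 1 each) in midbrain at 6 weeks, 24 weeks and 18 months, and 2 and 0 and 2 and 1 (value 1 each) in liver at 6 and 24 weeks. In cerebellum they were 29 and 0, 15 and 0 (value 1 each), 88 and 6079 (value 2) and 5020 and 569 (value 1), and a split that calls 6079 probe sets at 24 weeks points to structure among those arrays other than genotype.

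With 100 splits, a result met the rule set beforehand where fewer than 5 splits reached the real count. The averaged difference met it in striatum (value 1, 5037 against 1745), midbrain (2, 55 against 298), cerebellum (4, 159 against 646) and liver (1, 4 against 1). So did variation with age in striatum (2, 3688 against 3993) and midbrain (2, 742 against 783), 18 months against 6 weeks in striatum (2, 5030 against 5940) and midbrain (3, 6 against 24), and regions (4, 630 against 2670). These values were not adjusted for the number of tests, so values of 2 to 4 do not exclude chance. Pink1, whose loss defines the labels, is among the averaged calls, with 2 of the 4 in liver. In striatum low array mean equals genotype at 18 months, so the splits cannot tell them apart. The rule was not met for variation with age in cerebellum (17, 134 against 6282) and liver (100, 0 against 1) or for 18 months against 6 weeks in cerebellum (6, 57 against 1007). Age effects at 24 weeks passed in striatum (1, 5135 against 1054), midbrain (1, 4365 against 3331) and cerebellum (1, 1605 against 689) and not in liver (100, 0 against 3), and those at 18 months passed in all 3 (value 1 each, 18100 against 9718, 12780 against 3440 and 19282 against 11567). No set of gene lists met the rule: between genotypes 22 splits reached the count in striatum (10 against 17), 50 in midbrain (5 against 13), 6 in cerebellum (12 against 18) and 70 in liver (5 against 16). Between ages 40 did in striatum (5 against 14), 10 in midbrain (11 against 15), 19 in cerebellum (8 against 11) and 18 in liver (13 against 18), so every list shift in the report is open to chance.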

How the results depend on the processing

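The array-mean block, the technical-axis covariate, knockout arrays only, the midbrain average without the 24-week arrays, the region test, gene lists and overlap between regions without the 18-month arrays, the region test with a block for the same number across regions, and the tests that left out low-mean 18-month arrays, doubted liver wild types or liver arrays of large Gapdh difference were chosen after seeing the data. All other alternatives were fixed before the data were examined. Pink1 fell in all 370 of its 370 values under alternatives other than leaving out 1 array. With left-out arrays included, its log2 differences on both probe sets, at single ages and averaged, ran from -4.80 to -3.63 in striatum, -4.18 to -3.52 in midbrain, -5.19 to -3.61 in cerebellum and -5.50 to -4.19 in liver, with a largest adjusted p of 0.0131. Of 2033 values of the other named genes under alternatives other than leaving out 1 array, 1793 kept direction and side of the threshold, 202 kept direction and lost the call, 17 kept direction and gained one, and 21 reversed. Of 445 values of lists, 281 kept direction and side of the threshold and 164 lost the call. Of 351 counts of probe sets, 193 stayed within 1.5 times the reported count and 158 did not. Of 51 counts of lists 32 stayed within it and 19 did not. The values of those that moved follow, for each alternative, and the cause was not tested unless named. The number of arrays, 2 or 3 in a group, limits the precision of every value. The alternative on linear values was not run because the deposited values are log2, and a block for array mean could not be estimated for the striatum at 18 months, where it equals genotype.

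Striatum counts with 1 probe set per gene were 6 at 6 weeks, 4 at 12 weeks, 1 at 24 weeks, 5111 at 18 months, 2347 averaged over ages, 1829 for the 18-month interaction, 1388 for the F test over ages, 2080 for the 24-week age effect and 7247 for the 18-month age effect. Midbrain counts with 1 probe set per gene were 4 at 6 weeks, 1 at 12 weeks, 799 at 24 weeks, 2 at 18 months, 18 averaged over ages, 0 for the 18-month interaction, 197 for the F test over ages, 1360 for the 24-week age effect and 5250 for the 18-month age effect. Cerebellum counts with 1 probe set per gene were 7 at 6 weeks, 6 at 12 weeks, 251 at 24 weeks, 1903 at 18 months, 826 for the 24-week age effect and 8652 for the 18-month age effect. Liver counts with 1 probe set per gene were 1 at 6 weeks, 1 at 12 weeks, 1 at 24 weeks and 2 averaged over ages, and the region test called 255. Fewer probe sets are tested there by construction. Striatum counts with a filter at the median signal were 7209 at 18 months, 2934 for the 18-month interaction, 2259 for the F test over ages and 11920 for the 18-month age effect. The first 2 split into 620 rises and 6589 falls and into 303 and 2631. Midbrain calls with this filter were 1139 for the F test over ages. Cerebellum counts with it were 691 at 24 weeks, 637 averaged over ages, 364 for the 18-month interaction and 715 for the F test over ages. Striatum counts with the Gapdh covariate were 8 at 12 weeks and 641 for the 24-week age effect. Midbrain counts with the Gapdh covariate were 842 at 24 weeks, 25 averaged over ages, 380 for the F test over ages, 91 for the 24-week age effect and 38 for the 18-month age effect. Cerebellum counts with the Gapdh covariate were 25 at 12 weeks, 21 at 24 weeks, 25 at 18 months, 62 averaged over ages, 4 for the 18-month interaction, 30 for the F test over ages and 517 for the 24-week age effect. In liver it gave 8 at 6 weeks, 9 averaged over ages and 217 for the 24-week age effect, and the region test called 122. Striatum counts with array weights were 667 at 12 weeks, 3186 at 24 weeks, 9553 averaged over ages, 8192 for the 18-month interaction, 10144 for the F test over ages and 8798 for the 24-week age effect. Midbrain counts with array weights were 26 at 12 weeks, 8949 at 24 weeks, 36 at 18 months, 133 averaged over ages, 4490 for the F test over ages and 6905 for the 24-week age effect. Cerebellum counts with array weights were 124 at 6 weeks, 68 at 12 weeks, 9040 at 24 weeks, 13929 at 18 months, 11039 averaged over ages, 8260 for the 18-month interaction, 13445 for the F test over ages and 6455 for the 24-week age effect. In liver they gave 18 at 6 weeks, 14 averaged over ages and 87 for the 24-week age effect, and the region test called 9898. Striatum counts with quantile normalization were 6880 at 18 months, 2358 averaged over ages and 3052 for the 18-month interaction. In cerebellum it gave 469 at 24 weeks, and the region test called 158. With it the split into rises and falls was 4068 and 2812 in striatum at 18 months, 1349 and 1009 averaged over ages, and 2076 and 976 for the 18-month interaction. Midbrain counts with a trended and robust prior were 13 at 12 weeks and 1150 for the F test over ages. In cerebellum it gave 504 at 24 weeks, 304 averaged over ages, 192 for the 18-month interaction and 585 for the F test over ages. In liver it gave 1 for the 24-week age effect. Striatum calls with the Xist covariate were 44 at 12 weeks. Midbrain counts with it were 18 at 12 weeks and 2232 for the 24-week age effect. Cerebellum counts with it were 36 at 24 weeks, 83 averaged over ages, 34 for the F test over ages and 582 for the 24-week age effect. A fit of that age only called 7 at 12 weeks and 4 at 24 weeks in striatum. In midbrain it called 593 at 24 weeks and 5 at 18 months. In cerebellum it called 23 at 12 weeks, 5 at 24 weeks and 1218 at 18 months, and in liver 4 at 6 weeks. Wild-type arrays only gave 335 calls in striatum, 315 in cerebellum and 48 in liver for the 24-week age effect. For the 18-month age effect they gave 6384 in striatum, 6389 in midbrain and 10827 in cerebellum. Averaged calls without the 18-month arrays were 61 in striatum and 48 in cerebellum.

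Midbrain counts with the array-mean block were 7 at 18 months and 1121 for the F test over ages. In cerebellum it gave 247 at 24 weeks, 6 at 18 months and 55 averaged over ages. It gave 2 for the 18-month interaction and 11 for the F test over ages. Midbrain calls with the technical-axis covariate were 96 averaged over ages. In cerebellum it gave 310 at 24 weeks, 459 averaged over ages and 137 for the 18-month interaction, and the region test called 1260. For that test the components of the regions were turned to the same side, after the count was seen to depend on their arbitrary signs. Knockout arrays only gave 1122 calls in striatum, 8 in midbrain, 27 in cerebellum and 1 in liver for the 24-week age effect. For the 18-month age effect they gave 4461 in midbrain. The 18-month age effect without the low-mean arrays had 8111 calls in striatum and 8719 in cerebellum. In those 2 tissues no knockout array of 18 months is then left, so these counts rest on wild-type arrays. The region test with the 18-month arrays left out called 12, and with a block for the same number across regions 125. Without these arrays 21 averaged calls were shared in all 3 regions in the same direction, besides the pairs above. Liver counts with the 2 liver arrays of largest Gapdh difference left out were 5 at 6 weeks, 11 averaged over ages and 239 for the 24-week age effect. Without both doubted liver wild types they were 1 for the F test over ages and 4 for the 24-week age effect.

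For lists, an estimated correlation left 0 past the threshold in each of the 8 tests (10, 5, 12 and 5 between the genotypes in striatum, midbrain, cerebellum and liver, and 5, 11, 8 and 13 for age, in the same order, with the preset correlation). The fry test, which asks whether a list's genes move on balance in 1 direction, called 0 lists in midbrain and 0 in liver between the genotypes and 7 in cerebellum, and for age 23 in striatum, 17 in midbrain, 26 in cerebellum and 4 in liver. Midbrain genotype lists numbered 2 with the mean of a gene's probe sets, 2 with the technical-axis covariate and 3 without the 18-month arrays. Striatum age lists with quantile normalization numbered 1.

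Reversed log2 differences outside the left-out arrays were all of genes that had not passed in that tissue, except those of age. In liver, Nfu1 was 0.025, Paqr7 0.088, Sbsn -0.028 and Sike1 -0.071 with the Gapdh covariate. With array weights Nfu1 was 0.088, Paqr7 0.18, Phgdh -0.007, Sbsn -0.10, Sike1 -0.10 and Zfp9 0.013. Without the 2 liver arrays of largest Gapdh difference Nfu1 was 0.077, Paqr7 0.19, Sbsn -0.10, Sike1 -0.12 and Zfp9 0.024. Liver Sike1 was -0.007 with quantile normalization, and midbrain Sike1 was -0.004 without the 18-month arrays. The age effect of Rgs16 in midbrain at 18 months was 0.31 with the Gapdh covariate, which follows age there. In knockout arrays only, the age effect of Phgdh was -0.28 in cerebellum at 24 weeks and -0.30 in midbrain at 18 months, and that of Slc12a5 was 0.23 in midbrain at 24 weeks. Among genes with a liver value that did not pass, the averaged liver log2 difference ran, with 1 array left out, for Mid1 from -0.78 (without WT 12 weeks replicate 2) to 0.09 (without WT 12 weeks replicate 1), Nfu1 from -0.15 (without KO 24 weeks replicate 1) to 0.10 (without KO 24 weeks replicate 2), Paqr7 from -0.24 (without KO 24 weeks replicate 1) to 0.24 (without KO 24 weeks replicate 2). It ran for Sbsn from -0.10 (without KO 24 weeks replicate 2) to 0.13 (without KO 24 weeks replicate 1), Sike1 from -0.16 (without KO 24 weeks replicate 2) to 0.14 (without KO 24 weeks replicate 3). It also ran for Srsf10 from -0.31 (without KO 24 weeks replicate 2) to 0.09 (without KO 24 weeks replicate 3) and for Zfp9 from -0.28 (without WT 12 weeks replicate 2) to 0.033 (without WT 12 weeks replicate 1).

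With 1 array left out at a time, the ranges of the counts that moved by over 1.5 times are given with the arrays at their ends. The striatum 6-week count ran from 14 (without WT replicate 3) to 55 (without WT replicate 1). The striatum 12-week count ran from 8 (several arrays) to 132 (without KO replicate 3). The striatum 24-week count ran from 5 (several arrays) to 115 (without WT replicate 2). The striatum averaged count ran from 3299 (without KO 6 weeks replicate 2) to 7144 (without WT 24 weeks replicate 2). The striatum 18-month interaction count ran from 3141 (without KO 6 weeks replicate 3) to 5724 (without WT 6 weeks replicate 1). The striatum F test count ran from 1868 (without WT 18 months replicate 2) to 4980 (without WT 24 weeks replicate 3). The striatum 24-week age effect count ran from 3052 (without KO 6 weeks replicate 1) to 5620 (without WT 24 weeks replicate 2). The midbrain 6-week count ran from 11 (without KO replicate 3) to 19 (without WT replicate 2). The midbrain 12-week count ran from 3 (without KO replicate 3) to 6 (without WT replicate 2). The midbrain 24-week count ran from 1144 to 5231 (arrays as above). The midbrain 18-month count ran from 6 (without KO replicate 2) to 10 (without KO replicate 1). The midbrain averaged count ran from 32 (without WT 12 weeks replicate 1) to 115 (without KO 24 weeks replicate 3). The midbrain 18-month interaction count ran from 2 (several arrays) to 4 (without WT 18 months replicate 3). The midbrain F test count ran from 214 to 1673 (arrays as above). The midbrain 24-week age effect count ran from 2734 (without KO 6 weeks replicate 3) to 5371 (without KO 24 weeks replicate 2). The cerebellum 6-week count ran from 16 (without WT replicate 1) to 22 (without WT replicate 2). The cerebellum 12-week count ran from 5 (several arrays) to 7 (without WT replicate 3). The cerebellum 24-week count ran from 5 (several arrays) to 3038 (without WT replicate 1). The cerebellum 18-month count ran from 1397 to 8921 and the averaged count from 53 to 2201 (arrays as above). The cerebellum 18-month interaction count ran from 4 to 2670 (arrays as above). The cerebellum F test count ran from 9 to 2800 and the 24-week age effect count from 619 to 4122 (arrays as above). The liver 12-week count ran from 2 (several arrays) to 5 (without WT replicate 2). The liver 24-week count ran from 2 (several arrays) to 1259 (without KO replicate 3). The liver averaged count ran from 2 to 13 (arrays as above). The liver F test count ran from 0 (several arrays) to 87 (without KO 24 weeks replicate 1). The liver 24-week age effect count ran from 0 (several arrays) to 693 (without KO 24 weeks replicate 1). The region test count ran from 42 to 2537 (arrays as above).

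Arrays of the 2 genotypes with the same number were not pairs by their values: the correlation of their deviations from the group means ran from -0.68 to 0.41. The fit with the replicate number as a block is therefore given for its values only, and a lost call under this replicate block says nothing on the size of an effect. Striatum counts with the replicate block were 8 at 12 weeks, 4 at 24 weeks, 3160 averaged over ages and 1774 for the F test over ages. Midbrain counts with it were 16 at 6 weeks, 4 at 12 weeks, 7 at 18 months and 282 for the F test over ages. Cerebellum counts with it were 15 at 6 weeks, 8 at 12 weeks, 9 at 24 weeks, 2184 at 18 months, 46 averaged over ages, 4 for the 18-month interaction and 8 for the F test over ages. Liver calls with it were 2 averaged over ages, and the region test called 36.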

Other observations

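The 18-month arrays differed from younger ones in the labelling control Dap as well as in age. Ppargc1a, the coactivator of mitochondrial biogenesis, rose with age at 18 months in striatum (1.92), midbrain (1.11) and cerebellum (0.93), where many respiratory chain genes fell. The clock gene Ciart fell with age in all 3 regions (-0.96, -0.96 and -0.996). Syn2 rose in all 3 (0.82, 0.56 and 0.58), and the tight junction gene Cldn5 did so as well (0.85, 0.72 and 0.99).

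Hk2 in cerebellum was 7.64 ± 0.06 in KO and 8.45 ± 0.05 in WT at 6 weeks, and 7.87 ± 0.20 and 8.01 ± 0.10 at 18 months. A change of this difference with age was not shown (F test, adjusted p = 0.152, and 0.122 for 18 months against 6 weeks).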
